A study of Homo sapiens with 9 samples.

How the data were processed

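Gene expression was measured by microarray in HuH7 cells, a human hepatoma line, after transfection with an antisense oligonucleotide or with mock. Per the labels' protocols, cells were exposed for 4 h to 10 nM oligonucleotide or mock in 5 ug/ml lipofectamine, the medium was replaced, and RNA was taken 20 h later, 24 h after transfection. Biotin-labelled cDNA was made from 100 ng of total RNA by an Affymetrix protocol. The 9 arrays form 3 groups of 3 biological replicates: SPC3302, SPC3833 and mock. The labels give neither the sequence, the chemistry nor the target of either oligonucleotide.

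The authors deposited a single table of log2 signal, with 1 value per array for each of 21996 probe sets. The affy package was used, per the submitters' processing notes, with no version or steps given; the array model, the annotation release, the genome build, the background correction and the normalization are not given in the sources used here. That the deposited values are log2 was read from their range (1.04 to 13.3). The array medians were nearly equal (5.58 to 5.64), as after a scaling between arrays, but how the arrays were scaled is unknown. In 62.5% of the probe sets at least 2 arrays held exactly the same value. No scanner files, detection calls or background signals were used here, so whether a dim gene was above background was not judged. The number of arrays limits the precision.

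Each probe set is named by an Ensembl gene identifier, and every identifier occurs once, so a probe set is called a gene below. The table does not pair identifiers with gene symbols, and 0 of the 21996 identifiers matched an Ensembl entry of the gene table used here. Gene names, positions and functions are therefore not given, the 28 gene lists fixed before the data were examined could not be tested, and the single genes that had been set down to be reported in every comparison could not be looked up. The rule fixed for named genes took, in each comparison, the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap, with members of the gene lists and, for both comparisons with mock together, the 10 largest common changes. As no gene could be named, it was narrowed, once this was known, to 2 identifiers that rose and 2 that fell. These are the largest fall and the largest rise of each comparison with mock, or the next in order where both comparisons gave the same one.

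The deposited log2 values were fitted without further normalization with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 9 arrays in 1 fit of group means, 6 residual degrees of freedom, prior of 2.98 degrees of freedom). Contrasts were SPC3302 against mock, SPC3833 against mock and SPC3302 against SPC3833. Tests were two-sided, Benjamini-Hochberg adjustment was over all 21996 genes, and the threshold was an adjusted p of 0.05; intervals are 95% intervals of the moderated fit. A moderated F test asked which genes differed among the 3 groups. The arrays are labelled as biological replicates, and p-values reflect the spread between them. The fit used 1 variance per gene for all groups, while the mean variance was 0.0321 in mock, 0.0176 in SPC3302 and 0.0193 in SPC3833. Standard errors, intervals and p-values may therefore be too small against mock and too large between the oligonucleotides. The labels give no batch.

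Both comparisons with mock use the same 3 mock arrays. Unchanged groups sharing them were therefore simulated 100 times, with the spread of each group and the moderated variance of each gene. As moderation lowers the mean variance, 100 simulations with the unmoderated variances were added after seeing the data, and their covariance is the one set beside the observed value. The fit was tested on simulated data with 200 changed genes among 21996. These data had 1 moderated variance per gene for all groups. The larger spread of the mock arrays was left out, so recovery in the comparisons with mock may be overstated. At a log2 change of 0.5 it recovered 67.2% of the changed genes for SPC3302 against mock, 64.2% for SPC3833 against mock and 68.7% for SPC3302 against SPC3833. At a log2 change of 1 it recovered 100% (67 of 67), 98.5% (66 of 67) and 100% (67 of 67).

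Alternatives fixed before the data were examined were quantile normalization, centring each array on its median, leaving out the dimmest 30% of genes, an intensity trend or robust estimation in eBayes, array weights, fitting only the 2 groups compared, the replicate number as a block, and leaving out each array in turn. A single probe set per gene left alternatives on the choice of probe set with nothing to change, and they were not run. Weights per group, leaving out genes with tied values and setting each oligonucleotide against a different mock array were added after seeing the data.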

Results

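The transcript levels of 21996 genes were measured in HuH7 hepatoma cells 24 h after transfection with the antisense oligonucleotide SPC3302, with the antisense oligonucleotide SPC3833 or with mock, in 3 biological replicates each. Antisense oligonucleotides are short synthetic nucleic acid strands that pair with complementary RNA. Both were given at 10 nM, so that their responses can be set side by side at 1 dose and 1 time. Array medians lay between 5.58 and 5.64 on the log2 scale. Replicate arrays correlated across genes by 0.996 to 0.997 within SPC3302, by 0.995 to 0.996 within SPC3833 and by 0.992 to 0.995 within mock. Arrays of different groups correlated by 0.990 to 0.996, a range that holds all of the mock values. The mock arrays spread more than the others, with a median SD per gene of 0.113 (log2, n = 3), against 0.075 for SPC3302 and 0.080 for SPC3833. Of all genes, 458 differed among the 3 groups at an adjusted p under 0.05 in limma's moderated F test. This count was 235 to 643 when 1 array was left out.

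The first comparison asked which transcripts changed with SPC3302. In cells given SPC3302, 86 genes fell and 34 rose against mock, which is 0.546% of the genes tested. Falls were deeper than rises were high. The median fall was -0.63 and the median rise 0.43 on the log2 scale, and of the changes over 2-fold 16 were falls and none was a rise. The deepest fall was that of ENSG00000137942, whose signal went from 8.20 ± 0.09 in mock to 5.48 ± 0.21 (log2, SD, n = 3). This left 15.2% of the mock level, with a log2 fold change of -2.72 (SE 0.14, 95% interval -3.03 to -2.41, limma adjusted p = 9.68e-05). The largest rise was that of ENSG00000210144, from 9.24 ± 0.21 to 10.1 ± 0.02, a log2 fold change of 0.83 (SE 0.11, limma adjusted p = 0.012).

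With the scaling of the arrays the split moved to 82 falls and 48 rises after quantile normalization (63.1% falls) and to 69 and 17 after median centring (80.2% falls). The values of the groups did not overlap in any of the 120 changed genes; they did not overlap in 13.7% of all genes, where chance gives 10%. Which genes passed changed with the arrays used. In limma 38 genes, of which 36 fell, were called whichever of the 6 arrays was left out. The count was 57, 42 and 42 without SPC3302 replicates 1, 2 and 3. It was 273, 85 and 58 without mock replicates 1, 2 and 3. Fewer arrays lower the counts by construction, so the lower counts do not single out an array. In a fit of these 6 arrays alone limma called 32 genes, all of them falls, and 854 genes rose at an unadjusted p under 0.05; the rise of ENSG00000210144 was not past the threshold there (adjusted p = 0.079) nor without any 1 SPC3302 array, with a range over all alternatives of 0.0057 to 0.079.

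More genes passed the test with SPC3833. Against mock, 470 genes fell and 137 rose, 2.76% of the genes tested. The median fall was -0.50 and the median rise 0.41 on the log2 scale. Over 2-fold, 54 genes fell and 1 rose. ENSG00000137942 again fell the most, to 5.54 ± 0.24, which is 15.8% of the mock level (log2 fold change -2.66, SE 0.14, limma adjusted p = 5.88e-05). The next was ENSG00000156026, whose mock signal was 7.80 ± 0.12 and which fell to 21.8% of the mock level (log2 fold change -2.20, SE 0.11, limma adjusted p = 5.88e-05). The 1 rise over 2-fold was that of ENSG00000200115, from 4.78 ± 0.48 to 5.87 ± 0.23, a log2 fold change of 1.09 (SE 0.23, limma adjusted p = 0.043).

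The balance between falls and rises moved with the scaling of the arrays. After quantile normalization limma called 402 falls and 224 rises for SPC3833, so that falls made up 64.2% of the calls against 77.4% with the deposited values, while over 2-fold they still numbered 48 against 1 rise; after median centring it called 459 falls and 105 rises (81.4% falls). Of the 607 genes, 231 were called whichever of the 6 arrays was left out, 213 of them falls and 18 rises; the count was 322, 286 and 277 without SPC3833 replicates 1, 2 and 3, 1035 and 382 without mock replicates 1 and 3, and 240 in a fit of these 6 arrays alone. The rise of ENSG00000200115 was lost without either of mock replicates 1 and 2 (limma adjusted p = 0.085 and 0.13) and with any SPC3833 array left out, with a range over all alternatives of 0.0080 to 0.15. The values of the groups did not overlap in any of the 607 genes, nor in 17.2% of all genes, where chance gives 10%.

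**Figure D1:**
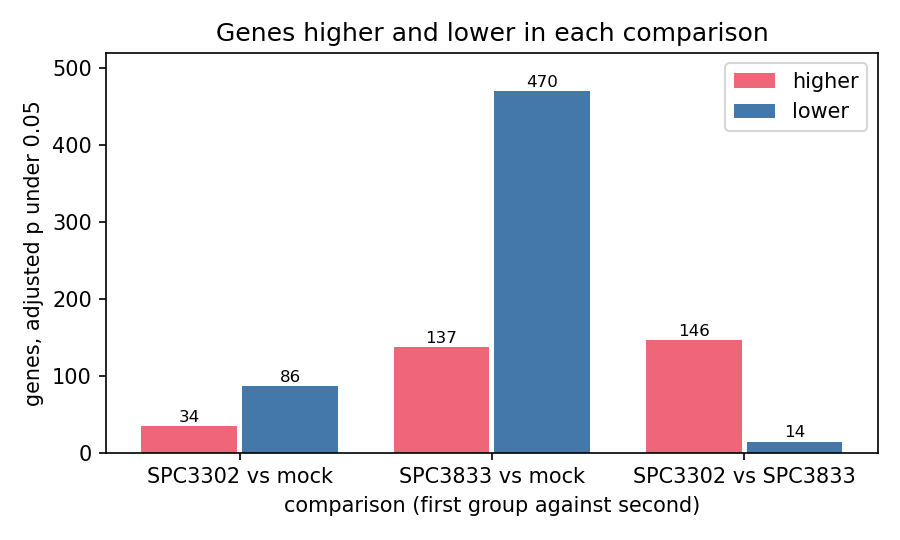
Number of genes (vertical axis) past an adjusted p of 0.05 in limma, for each comparison of the first-named group against the second. Falls outnumber rises against mock (86 against 34 and 470 against 137), and 146 of the 160 genes that differ between the oligonucleotides were higher with SPC3302.

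**Figure D2:**
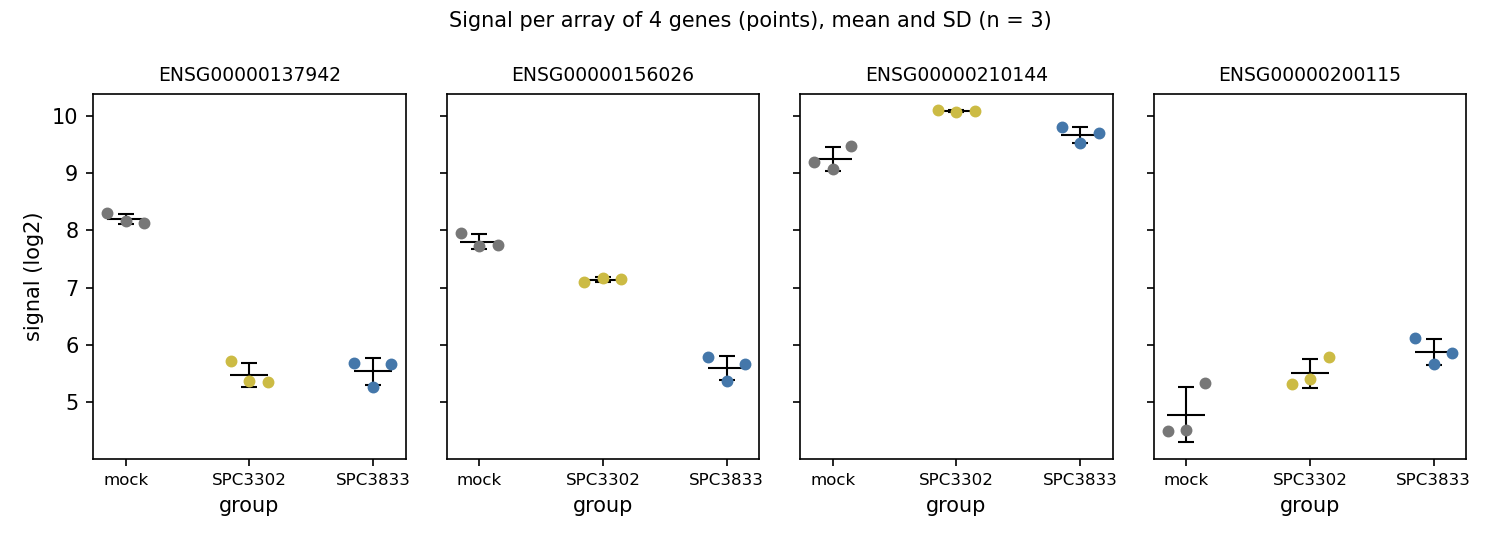
Deposited log2 signal (vertical axis) of 4 genes on each array (points) in the 3 groups, with the mean and SD (n = 3) as bars. ENSG00000137942 drops to 15.2% of the mock level with SPC3302 and to 15.8% with SPC3833, while ENSG00000156026 lies at 21.8% of the mock level with SPC3833 and at 63.1% with SPC3302.

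Both oligonucleotides changed a common set of genes in the same direction. Of the genes that fell with SPC3302, 64 of 86 also fell with SPC3833, and of those that rose 23 of 34 also rose. No gene called in both comparisons went in opposite directions. Independent lists of these lengths would share 1.84 falls and 0.212 rises, and simulated unchanged groups measured against the same mock arrays shared at most 1 gene, a value that leaves out real effects and so does not give the part of the overlap that comes from the shared arrays. The 64 common falls had a median log2 fold change of -0.65 with SPC3302 and -0.75 with SPC3833, and the 23 common rises of 0.43 and 0.42. In 9 genes the fall was over 2-fold with both. Across all genes, which are not independent replicates, the log2 fold changes of the 2 oligonucleotides correlated with r = 0.702 and had a covariance of 0.0211. Their signs were the same in 76.0% of genes, against a mean of 71.9% in the simulated unchanged groups. The shared mock arrays alone gave a mean r of 0.634 and a mean covariance of 0.0106 in simulations with unmoderated variances, a difference in covariance of 0.0104; with moderated variances the simulated covariance was 0.00864. With a different single mock array for each oligonucleotide, r was 0.146 to 0.246 over the 6 combinations and the mean covariance 0.0104. This value and the difference of 0.0104 match by construction, since both take out the variance of the mock arrays. With 3 mock arrays no split leaves 2 on either side, so part of the overlap may come from the shared controls; the number of common genes was 230 and 47 without mock replicates 1 and 3 and 36 to 54 without any 1 oligonucleotide array, and 28 (26 falls) were called in both comparisons whichever array was left out.

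The direct comparison asked where SPC3302 and SPC3833 differ at the same dose and time. Of the 160 genes that differed, 146 were lower with SPC3833 and 14 lower with SPC3302, and 13 of the former differed by over 2-fold. Nearly all of these differences lay in genes that fell against mock. Of the 146, 143 had fallen with SPC3833, by a median of -0.74 on the log2 scale, where the median with SPC3302 was -0.11. Of the 14, 11 had fallen with SPC3302, by a median of -0.75, where the median with SPC3833 was -0.24. In each case the fall and the difference use the same oligonucleotide arrays, so noise there can meet both at once. Choosing genes this way can overstate the gap between the medians. Rises seldom differed: none of the 23 common rises, 2 of the 114 rises called with SPC3833 alone and none of the 11 called with SPC3302 alone passed the test of the difference. For ENSG00000137942 the oligonucleotides differed by -0.06 on the log2 scale, with a 95% interval of -0.36 to 0.25 (limma adjusted p = 0.99). ENSG00000156026 was 1.54 higher with SPC3302 than with SPC3833 (95% interval 1.30 to 1.78, limma adjusted p = 5.75e-04). Its own change with SPC3302 against mock was -0.67 (SE 0.11, limma adjusted p = 0.035), and this call was lost with any 1 of the 6 arrays left out (range over all alternatives 0.018 to 0.15).

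A call with 1 oligonucleotide and not the other did not by itself separate them. Of the 406 genes that fell with SPC3833 and were not called with SPC3302, 132 were lower with SPC3833 by the direct test; the other 274 had a median log2 fold change of -0.44 with SPC3833 and -0.24 with SPC3302. Of the 22 genes that fell with SPC3302 and were not called with SPC3833, 8 were lower with SPC3302 by the direct test. The 95% interval of a difference reached a median of 0.19 to either side on the log2 scale, and the smallest difference called was 0.30. The side lower with SPC3302 grew from 14 genes to 35 without the dimmest 30% of genes, beside 195 lower with SPC3833, and to 44 with array weights or weights per group, beside 229 and 216. Leaving out single arrays of these groups brought the 160 genes down to between 76 and 95; 69 genes were called in limma in every such fit, 65 of them lower with SPC3833 and 4 lower with SPC3302.

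**Figure D3:**
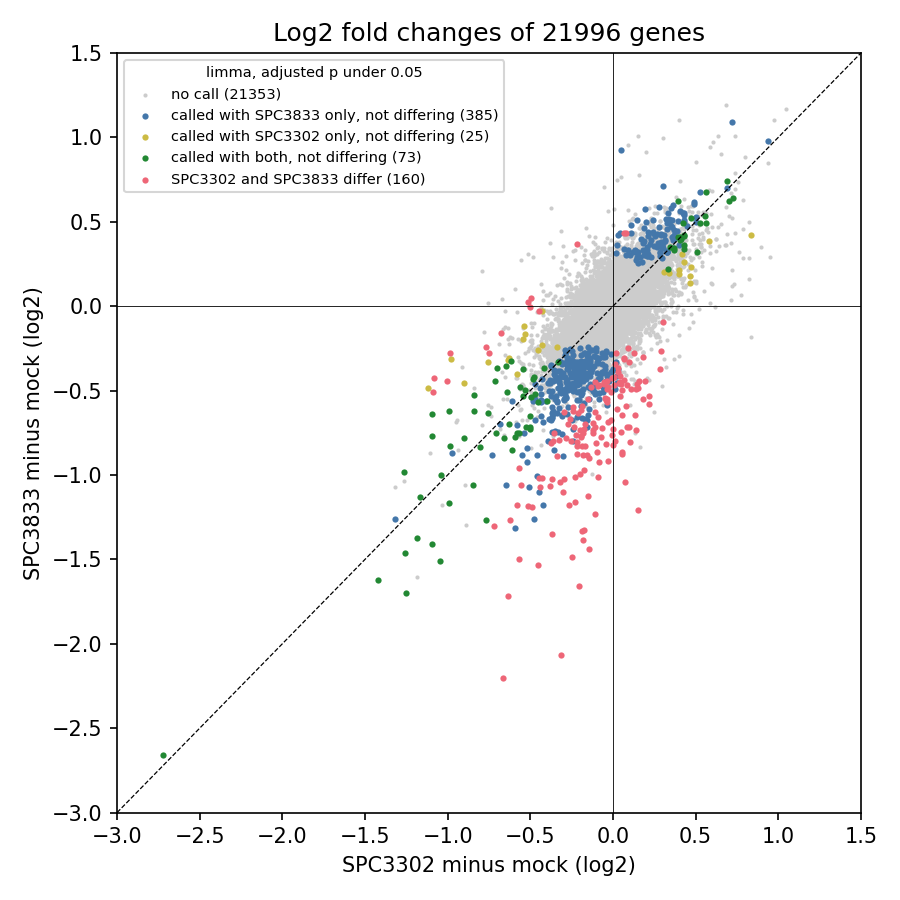
Log2 fold change of each gene with SPC3302 (horizontal axis) and SPC3833 (vertical axis) against mock; the dashed line marks equal change, colours mark calls at an adjusted p under 0.05 in limma, and the 160 genes that differ between the oligonucleotides are in red whatever their other calls. The red points lie mainly below the line among genes that fell with SPC3833, and ENSG00000137942 lies on the line at the lower left.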

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

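The tests with no mock array shared between comparisons, on single mock arrays for SPC3302, on mixed treated RNA in mock replicate 1, on the deviation of mock replicate 1 from the other mock arrays and on changes over 2-fold were chosen only after the result they bear on was seen.

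The responses to the 2 oligonucleotides were related, and they differed by the direct test in 160 genes, among them ENSG00000156026 (log2 difference 1.54, SPC3302 minus SPC3833, limma adjusted p = 5.75e-04, range over all alternatives 0.00017 to 0.011). Shared mock arrays are argued against as the whole cause of the relation, by a test added after the data were seen. With a different mock array for each oligonucleotide, which removes the shared part, the covariance was still 0.0104 on average (0.00741 at the lowest of 6 combinations) of 0.0211 in all. Of 840 regroupings of the arrays, 12, the real one included, gave as high a mean (highest 0.0122). The bound set beforehand was a covariance over 2 times the highest simulated one. It was met with moderated variances (highest 0.00919). With unmoderated variances (highest 0.0117) the covariance fell between the bounds set for either reading. The rest lies near the 0.0106 of simulations with no effect by construction, since both come from the variance of the mock arrays, and adds no support. Whether the response is the same and only stronger with SPC3833 stays undecided. There were 11 genes that fell against mock with SPC3302 and lay lower with it than with SPC3833, where at least 5 had been set beforehand to count against that reading. There were 5, 4 and 5 without SPC3302 replicates 1, 2 and 3, 6, 6 and 5 without those of SPC3833 and 17 without mock replicate 2, and 4 genes were called in every fit. Both conditions use the same SPC3302 arrays, so noise there can meet both at once. The count that noise alone would give was not worked out. Effects shared by any transfected oligonucleotide, and transcripts that both strands could pair with, stay open as untested, since the series holds no unrelated oligonucleotide and the sequences were not used here.

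Most genes called against mock fell, and a limited upper range of the signal is argued against by the genes with a mock signal of 6 to 10, of which 80.1% of those called with SPC3833 fell (398 of 497, exact 95% interval 76.3 to 83.5). A single mock array is argued against as the whole cause, for SPC3833, where the lowest share of falls was 65.6%, without mock replicate 1 (679 falls, 356 rises). That is only just past the bound set beforehand. For SPC3302 the lowest share was 61.9%, also without mock replicate 1 (169 falls, 104 rises). It lies between the bounds set for either reading, so a single mock array stays open for the whole set of SPC3302 calls. Of the 38 SPC3302 genes called whichever of the 6 arrays was left out, 36 fell. These 38 were chosen for passing without any 1 array, and the choice keeps large changes (median fall -0.875). Their share of falls therefore adds no support. For the whole set of SPC3833 calls an offset between arrays cannot be told apart from a real excess, because quantile normalization brought the share to 64.2%, between the bounds set for either reading. For SPC3833 changes over 2-fold it is argued against: falls made up 98% of these under quantile normalization (48 falls, 1 rise) and 98.2% under median centring (54 falls, 1 rise). Cleavage of transcripts paired with an oligonucleotide may give such falls and stays open, as untested.

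The mock arrays varied more than the others. Noise of dim genes is argued against as the cause, because the mean variance of mock was 2.62 times that of the oligonucleotide arrays in the 7332 brightest genes and 1.43 times in the 7332 dimmest. A fit without mock replicate 1 gave 142 genes that fell with both oligonucleotides. In these, that array lay a median of 59% of the way from the other mock arrays to the treated ones (middle 50% of genes -1.8 to 85.9%). The bootstrap 95% interval of the median was 41.9 to 69.5. It resamples genes of 1 array as if independent and leaves out the spread between arrays. Mock replicates 2 and 3 lay at 14% and 6.18% in their own fits, over 57 and 37 genes. Each set of genes was chosen on the other 2 mock arrays, which can draw the left-out array toward the treated ones. The nearness of mock replicate 1 is what treated RNA or oligonucleotide in that sample could give. No single share of treated RNA, taken at the mean of both treatments, left fewer than 29.6% of the 142 genes over 3 standard errors off. The 65 genes nearer to the other mock arrays had the deeper median fall (-0.70 against -0.47 for the other 77). This does not decide on 1 share of treated RNA. The standard errors pool the tighter oligonucleotide arrays, and no such count was made for another mock array. Exposure to oligonucleotide and a general nearness of mock replicate 1 to the treated arrays stay open: across all genes its deviation from the other mock arrays correlated with the treated difference by only 0.069 and 0.105, yet it correlated with the SPC3302 arrays by 0.99500 to 0.99577 and with the SPC3833 arrays by 0.99384 to 0.99479, against 0.99286 and 0.99458 with mock replicates 2 and 3, which larger noise of those 2 arrays could also give.

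Regrouping the arrays gave fewer calls. Of the 280 splits of the 9 arrays into 3 groups, 100 were drawn. Among these only the real split reached its 458 genes in the F test, a share of 1 in 100. The highest other, which keeps the SPC3833 arrays together, gave 131. A split by chance is thus argued against for this count, but not excluded. Splits that mix the groups put differences between the groups into the spread, which lowers their counts. Anything else that goes with the group is not told apart from the treatment. For each pair of groups 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts of 120, 607 and 160 stand against a highest other count of 0 in limma, with up to 1876, 1899 and 796 genes at an unadjusted p under 0.05 in those other splits, against 2475, 3552 and 1494 in the real ones.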

How the results depend on the processing

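Weights per group, leaving out genes with tied values and a different mock array per comparison were chosen after seeing the data. Under each alternative that gave counts of calls, falls outnumbered rises against mock and more genes were lower with SPC3833 than with SPC3302. For SPC3302 against mock (120 genes), limma called 187 without the dimmest 30% of genes, 32 with the 2 groups alone and 78 with the replicate block; for SPC3833 (607), 240 with the 2 groups alone; for the difference between the oligonucleotides (160), 273 with array weights and 260 with weights per group. Weights per group, which allow for the larger spread of mock, gave 90 genes for SPC3302 and 450 for SPC3833 against mock. Genes changed in both rose from 87 to 139 without the dimmest 30%. The covariance (0.0211) was 0.0347 without genes with tied values and 0.0104 with a different mock array per comparison, where r (0.702) was 0.206 on average, since single arrays add noise and share none. The replicate block gave 499 and 111 genes for the other comparisons; same-numbered arrays correlated by only -0.09 to 0.25 in their deviations from group means, and 2 of 9 correlated best with their own number. Leaving out 1 array gave 42 to 273 genes for SPC3302 (57, 42 and 42 without SPC3302 replicates 1, 2 and 3, and 273 and 58 without mock replicates 1 and 3), 277 to 1035 for SPC3833 (322, 286 and 277 without its replicates, 1035 and 382 without mock replicates 1 and 3), 76 to 95 for the difference, 36 to 230 for genes changed in both (230 and 47 without mock replicates 1 and 3), 235 (without SPC3833 replicate 1) to 643 (without mock replicate 1) in the F test, 0.0206 to 0.0315 for the covariance and 0.650 to 0.777 for r. Fewer arrays lower the counts by construction; the cause of the other changes was not tested, apart from the weighing of mock replicate 1. Of 192 values of the 4 identifiers under other settings, 169 kept direction and side of the threshold, 22 lost a call, 1 gained one and 0 reversed. Signal over background was not used here. Gene list tests and alternatives on the choice of probe set were not run, for want of gene names and of further probe sets per gene.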

Other observations

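Falls separated the oligonucleotides and rises hardly did. Among genes called with SPC3833 against mock and changed by 0.2 to 1.1 on the log2 scale, 123 of 432 falls (28.5%) and 2 of 137 rises (1.46%) differed between SPC3302 and SPC3833 in limma. Within 5 bins of matched size of change, the common odds ratio was 17.6 (exact 95% interval 4.54 to 151, treating genes as independent, which they are not). The pattern is consistent with falls that depend on the particular oligonucleotide beside rises that are common to both transfections, a hypothesis noticed in these data and tested on them. Rises that rest on chance in the shared mock arrays would look common too, and these data leave that open. Among genes called in every fit that left out 1 array, 2 of 18 rises (11.1%) and 116 of 213 falls (54.5%) still differed (Fisher's exact test, two-sided p = 3.6e-04, genes taken as independent). At matched size 93 of 176 such falls and 2 of 18 rises differed (common odds ratio 6.03, exact 95% interval 1.3 to 56.9), a test added after the first was seen. Each of these fits still shared mock arrays between the comparisons, so neither test decides, although the first had been set to count against the mock arrays. A mock treatment that lacks an oligonucleotide altogether could give the common rises and some common falls, which these 3 groups cannot separate.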
